A study of Homo sapiens with 66 samples.

How the data were processed

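Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on effector memory Th1 and effector memory Treg cells sorted from peripheral blood of 5 control donors and 6 donors with type 1 diabetes (T1D), per the labels. Each donor gave both cell types. Antibodies against H3K27ac, a histone mark of active promoters and enhancers, and against H3K4me1, a histone mark of enhancers, were used, and input DNA was sequenced as well. The 66 samples comprise 44 ChIP libraries, each with 1 peak list, and 22 inputs, which were not analysed here. The title of 1 H3K27ac library, Treg T1D replicate 2, carries an extra suffix after the mark. It was taken as an H3K27ac library, and whether it repeats an earlier one is not known. Its list was narrow and held 4715 autosomal peaks. Libraries were made with a kit for low DNA amounts and sequenced on 1 instrument model, per the labels' protocols.

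The submitters' processing notes name CASAVA 1.8, Bowtie2, MACS 1.4 and the human build hg19, without saying which step each tool served. Whether the inputs entered the peak calling is not given in the sources used here. The deposited files hold 1 peak list per library, so replicates were not pooled. Each peak has a start, an end and a score that the authors deposited. The lowest score of a list lay between 50 and 50.05 and the highest score of any list was 3233. The score was used only to filter or rank peaks within a list. The lists hold no read counts, so the sequencing depth is unknown, no counting interval can be given, and a missing peak can mean either less of the mark or fewer reads.

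For each mark, consensus regions were built on the autosomes from stretches of at least 200 bp where peaks of at least 3 of the 22 libraries overlapped, and stretches up to 200 bp apart were joined. A library had a region when at least 1 bp of the region lay under its peaks. Since list sizes differed several-fold, each library received a weight from a Rasch model, in which the logit of a peak's presence is the sum of a region term and a library term. Given the number of libraries with a peak in a region, the number in the first group was compared with its exact distribution under those weights, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over all regions of the mark, with a threshold of 0.05. The expected number of libraries quoted beside a region is the mean of that distribution. Th1 and Treg were compared over 11 against 11 libraries, and T1D and control over 6 against 5 within each cell type. The number of peaks, the covered length and the share of H3K27ac peaks that overlap an H3K4me1 peak of the same donor and cell type were compared by 2-sided exact permutation tests over all splits of the 11 donors, or by permutation tests with 100000 resamples between cell types.

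The labels tie the Th1 and the Treg library to a donor, so the replicate numbers pair the samples. No pairing was inferred from the peaks. Across the 11 donors, the number of H3K27ac peaks in Th1 and in Treg had a Pearson r of -0.13 (permutation p = 0.73, adjusted p = 0.838) and a Spearman rho of 0.073 (p = 0.838, adjusted p = 0.838). That Pearson r turned to 0.22 without the 2 donors farthest from the median. For H3K4me1 the Pearson r was 0.47 (permutation p = 0.139, adjusted p = 0.362) and the Spearman rho 0.44 (p = 0.181, adjusted p = 0.362), and r was 0.36 without the 2 donors farthest from the median. No 2 of the 44 lists were identical, and at most 0.013% of a list's peaks had the same start and end as peaks of another list of the mark.

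The test was checked on simulated presence tables drawn from the fitted model, with 200 regions changed in each. The changed regions were picked among those with a peak in an intermediate share of the libraries. The rates below therefore do not hold for regions with a peak in few or in nearly all libraries. The simulated tables held no pairing by donor and no effect of peak width, so how the test behaves with these was not checked. For H3K27ac between Th1 and Treg, 90 of 100 regions with an odds ratio of 1000 and 16 of 100 with an odds ratio of 30 were called, with 3 calls among 16984 unchanged regions. For H3K4me1 the numbers were 79 and 18 of 100, with 0 calls among 31038 unchanged regions. At the size of the T1D comparisons, between 9 and 18 of 100 regions with an odds ratio of 1000 and at most 1 of 100 with an odds ratio of 30 were called.

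The median peak width divided the lists into a narrow class, with medians from 160 to 478 bp, and a wide class, with medians from 935.5 to 2021 bp. A limit of 700 bp was set after the lists had been seen. Of the H3K27ac lists 5 were narrow and 17 wide, and of the H3K4me1 lists 15 were narrow and 7 wide. This class was treated as a technical batch, and the region test was repeated with the class as a stratum.

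The weighted test and its alternatives were fixed before the comparisons were run, but with the several-fold difference in list sizes already known. The alternatives were Fisher's exact test without weights, a score of at least 100, lists of equal length and coverage of at least 50% of a region. Also set then were regions of at least 2 or at least 6 libraries, the donor as a block and each disease group alone. The log2 scale for sizes and leaving out each donor in turn over the same regions completed them. The width class as a stratum, each class alone, a restricted set of tested regions, and the donor block and width classes for stretches of 100 kb were added after seeing the data. The rule for named regions was fixed at the same stage and took up to 10 called regions in each direction between cell types. In the T1D comparisons it took the called regions or, with none called, the 3 smallest unadjusted p-values in each direction. Ties went to the larger difference between the groups and then to genome position, so regions with the same p as a named one may go unnamed.

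No gene annotation of hg19 was used here. The planned promoter share of peaks, the scores of fixed gene lists in both comparisons, the difference of their T1D effects between cell types, the marker lists of other cell types and the naming of regions by the nearest gene were therefore not run, and regions are given by hg19 coordinates. During exploration, gene positions recalled from general knowledge of hg19 were tried and compared with those of a newer build. That step was withdrawn because neither is an annotation of the build of the files, and no value from it is reported. Its gene list and single-gene values had been seen before the stretches of 100 kb, the width class alternatives, the restricted set of regions and the tests that weigh explanations were chosen. The stretches named and the loci mapped were first picked by eye with that knowledge, and were then replaced by fixed rules, the smallest p-values for stretches and all called H3K27ac regions for maps. Chromosomes X and Y were left out throughout. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.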

Results

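H3K27ac and H3K4me1 were profiled in Th1 cells, the helper T cells that produce interferon gamma, and in Treg cells, the regulatory T cells that restrain immune responses, from 5 control and 6 T1D donors. Each mark had 5 Th1 control, 6 Th1 T1D, 5 Treg control and 6 Treg T1D lists. The study set out to predict enhancers in these cells from both marks. The H3K27ac lists held between 4604 and 21168 autosomal peaks and the H3K4me1 lists between 4532 and 54421. Consensus regions numbered 17184 for H3K27ac and 31238 for H3K4me1. A single library had a peak in 21.002% to 94.6% of the H3K27ac regions and in 11.2% to 92.1% of the H3K4me1 regions. Read depth is unknown from the peak lists.

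The size of the H3K27ac lists did not separate the cell types. Th1 lists held 13060 ± 3461 peaks (SD, n = 11) and Treg lists 11270 ± 4693 (SD, n = 11). This difference did not pass a test that leaves out the pairing by donor (permutation p = 0.322), nor one with the donor as a block (exact sign-flip permutation p = 0.396). They covered 20.8 ± 11.5 Mb in Th1 and 17.6 ± 14.1 Mb in Treg (permutation p = 0.563). Without T1D replicate 5 the difference in peak number went from 1791 to 314 and that in covered length from 3.21 to -0.115 Mb. H3K4me1 lists held 25314 ± 8387 peaks in Th1 and 22510 ± 14236 in Treg (permutation p = 0.585), and covered 23.8 ± 25.8 Mb and 15.8 ± 25.1 Mb (permutation p = 0.48). The difference of 2804 H3K4me1 peaks was 672 without T1D replicate 1, 792 without T1D replicate 4 and 5086 without T1D replicate 3.

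**Figure D1:**
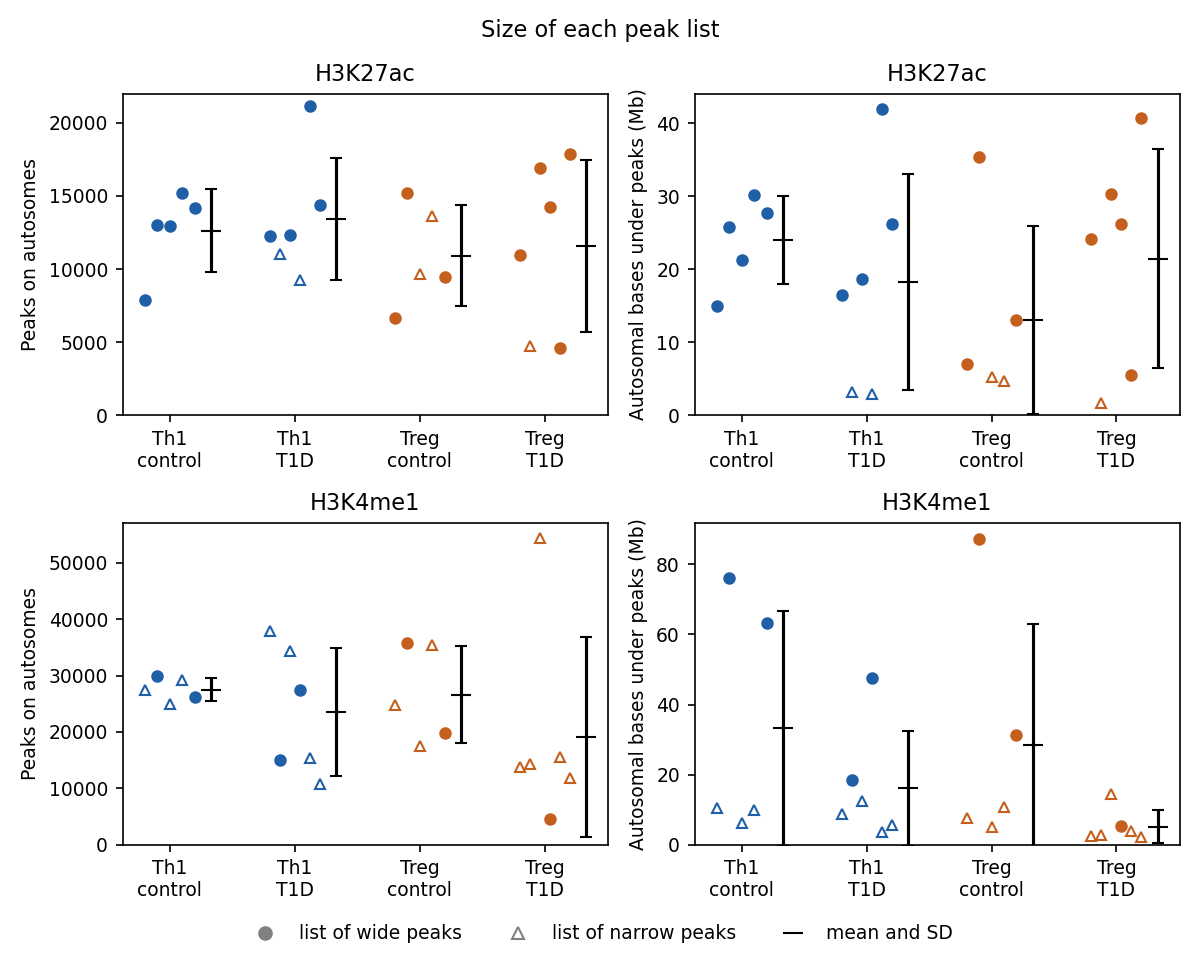
Number of autosomal peaks (left) and autosomal bases under peaks in Mb (right) for each H3K27ac (top) and H3K4me1 (bottom) list, by cell type and disease group; points are libraries, filled circles are lists of wide peaks, open triangles lists of narrow peaks, and the black mark gives the mean and SD, with lower bars ending at the axis where the SD exceeds the mean. The H3K4me1 lists of Treg cells from T1D donors covered 5.21 Mb on average, against 28.4 Mb in controls.

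In H3K27ac, 4 regions differed between Th1 and Treg by the exact conditional test with Benjamini-Hochberg adjustment, and all 4 had more Treg than Th1 libraries with a peak. A region on chromosome 19 from 5129496 to 5132564 (hg19) had a peak in 0 of 11 Th1 and 8 of 11 Treg libraries, where 4.45 and 3.55 were expected from list sizes (exact test, adjusted p = 0.00163). A second region of chromosome 19, from 42143900 to 42147366, had the same counts and the same adjusted p. On chromosome 6, the regions from 167506686 to 167508749 and from 167531167 to 167537250 each had a peak in 0 of 11 Th1 and 7 of 11 Treg libraries (exact test, adjusted p = 0.021 for each). At an unadjusted p under 0.05 there were 678 regions, of which 222 were higher in Th1 and 456 in Treg. With the donor as a block there were 459, with a near-even balance of 225 higher in Th1 and 234 in Treg. The balance turned by Fisher's exact test without library weights (212 higher in Th1, 24 in Treg), without T1D replicate 5 (246 and 160, 406 in all) and in T1D donors alone (173 and 131). With the donor as a block 1 region was called, that of chromosome 19 at 5129496 (exact test, adjusted p = 0.0242), and with the width class as a stratum 1 region was called, the same one (exact test, adjusted p = 0.00449). Without T1D replicate 5 the count was 0, and without T1D replicate 6 or without control replicate 1 it was 2.

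In H3K4me1, 8 regions differed between Th1 and Treg, 4 in each direction. Other settings divided the calls otherwise, with 0 higher in Th1 and 8 in Treg at 50% coverage, and 13 and 5 over regions able to reach a p under 0.001. Regions on chromosome 7 from 44929994 to 44932334 and on chromosome 15 from 26055636 to 26057905 had a peak in 11 of 11 Th1 and 0 of 11 Treg libraries (exact test, adjusted p = 0.00422 for each). Regions on chromosome 2 from 242812775 to 242814605 and on chromosome 11 from 36471246 to 36475658 had a peak in 10 of 11 Th1 and 0 of 11 Treg libraries (exact test, adjusted p = 0.0263 for each). Higher in Treg was a region on chromosome 19 from 42145453 to 42147226, with 0 of 11 Th1 and 9 of 11 Treg libraries (exact test, adjusted p = 0.00422), which lies within the called H3K27ac region at 42143900. A region on chromosome 10 from 6109483 to 6114324 had a peak in 3 of 11 Th1 and 11 of 11 Treg libraries (exact test, adjusted p = 0.0225). The remaining Treg-higher regions were on chromosome 12 from 62609809 to 62611083, with 0 and 8 libraries (exact test, adjusted p = 0.0225), and on chromosome 10 from 70815775 to 70817599, with 2 and 10 libraries (exact test, adjusted p = 0.0263). There were 1753 regions at an unadjusted p under 0.05, 838 higher in Th1 and 915 in Treg. Fisher's exact test without library weights gave 756, 683 higher in Th1 and 73 in Treg. The balance depended on the setting, from 251 higher in Th1 and 793 in Treg with 50% coverage, 257 and 568 in control donors alone, 117 and 469 among lists of wide peaks and 174 of 636 higher in Th1 among lists of narrow peaks, to the unweighted numbers. Th1-higher regions were also the more numerous with a score of at least 100 (270 and 253), with lists of equal length (181 and 154), with the width class as a stratum (857 and 728) and without T1D replicate 1 (726 and 595), 3 (834 and 756) or 4 (698 and 563). The donor block called 0 regions, with 776 at an unadjusted p under 0.05, 245 higher in Th1 and 531 in Treg. For the regions of chromosomes 7 and 15, all 11 donors had the peak in Th1 alone, so no clearer division by donor was possible. Their blocked p was still 0.00172 (exact test, unadjusted), which could not pass the adjustment here. The block therefore could not decide on these regions. With the width class as a stratum 5 regions were called. Leaving out 1 donor gave between 3 and 10 calls, with 3 without control replicate 1, 2, 4 or 5, 4 without control replicate 3 or T1D replicate 1, 2 or 5, and 5 without T1D replicate 6. Of the 8 regions named here, those on chromosomes 2 and 11 passed in 2 of the 11 sets that leave out 1 donor, and both on chromosome 10 and that on chromosome 12 in 3. Those on chromosomes 7 and 15 passed in 10 sets and that on chromosome 19 in 11. The 10 calls without T1D replicate 3 held 6 of the 8.

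**Figure D2:**
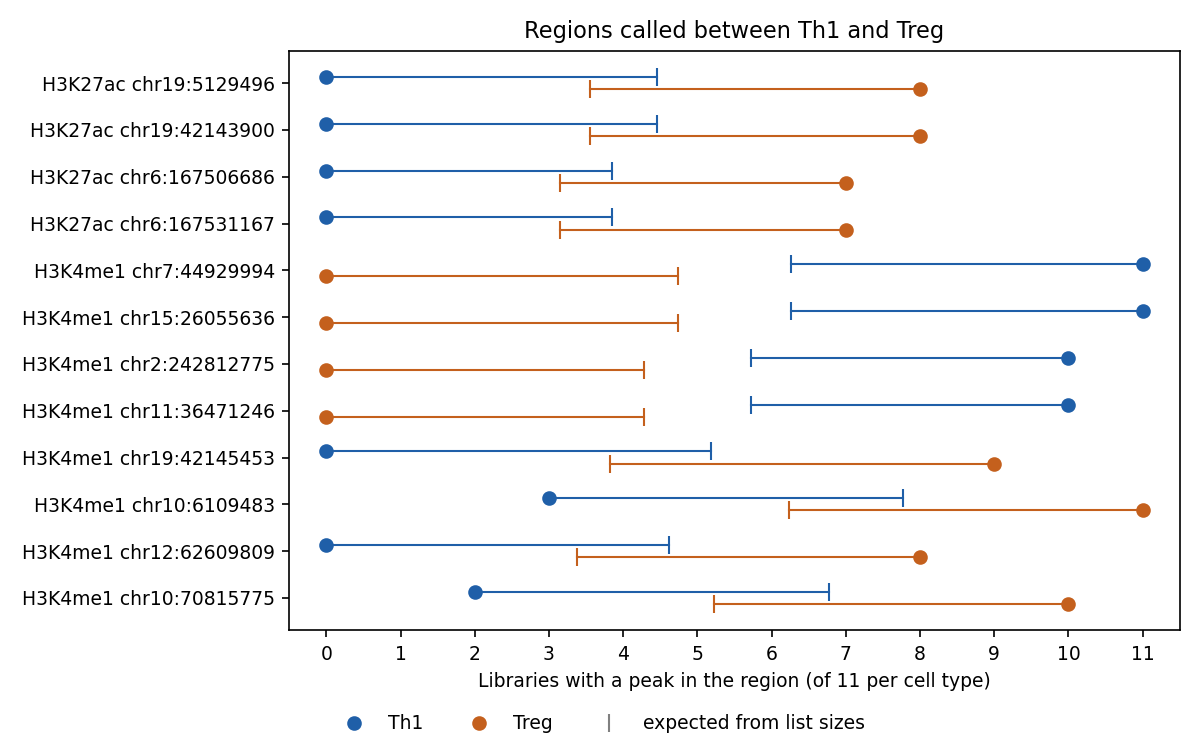
Number of libraries, of 11 per cell type, with a peak in each of the 12 regions called between Th1 and Treg; dots are observed numbers and vertical ticks the numbers expected from list sizes. The chromosome 7 and chromosome 15 regions had a peak in 11 Th1 and 0 Treg libraries.

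**Figure D3:**
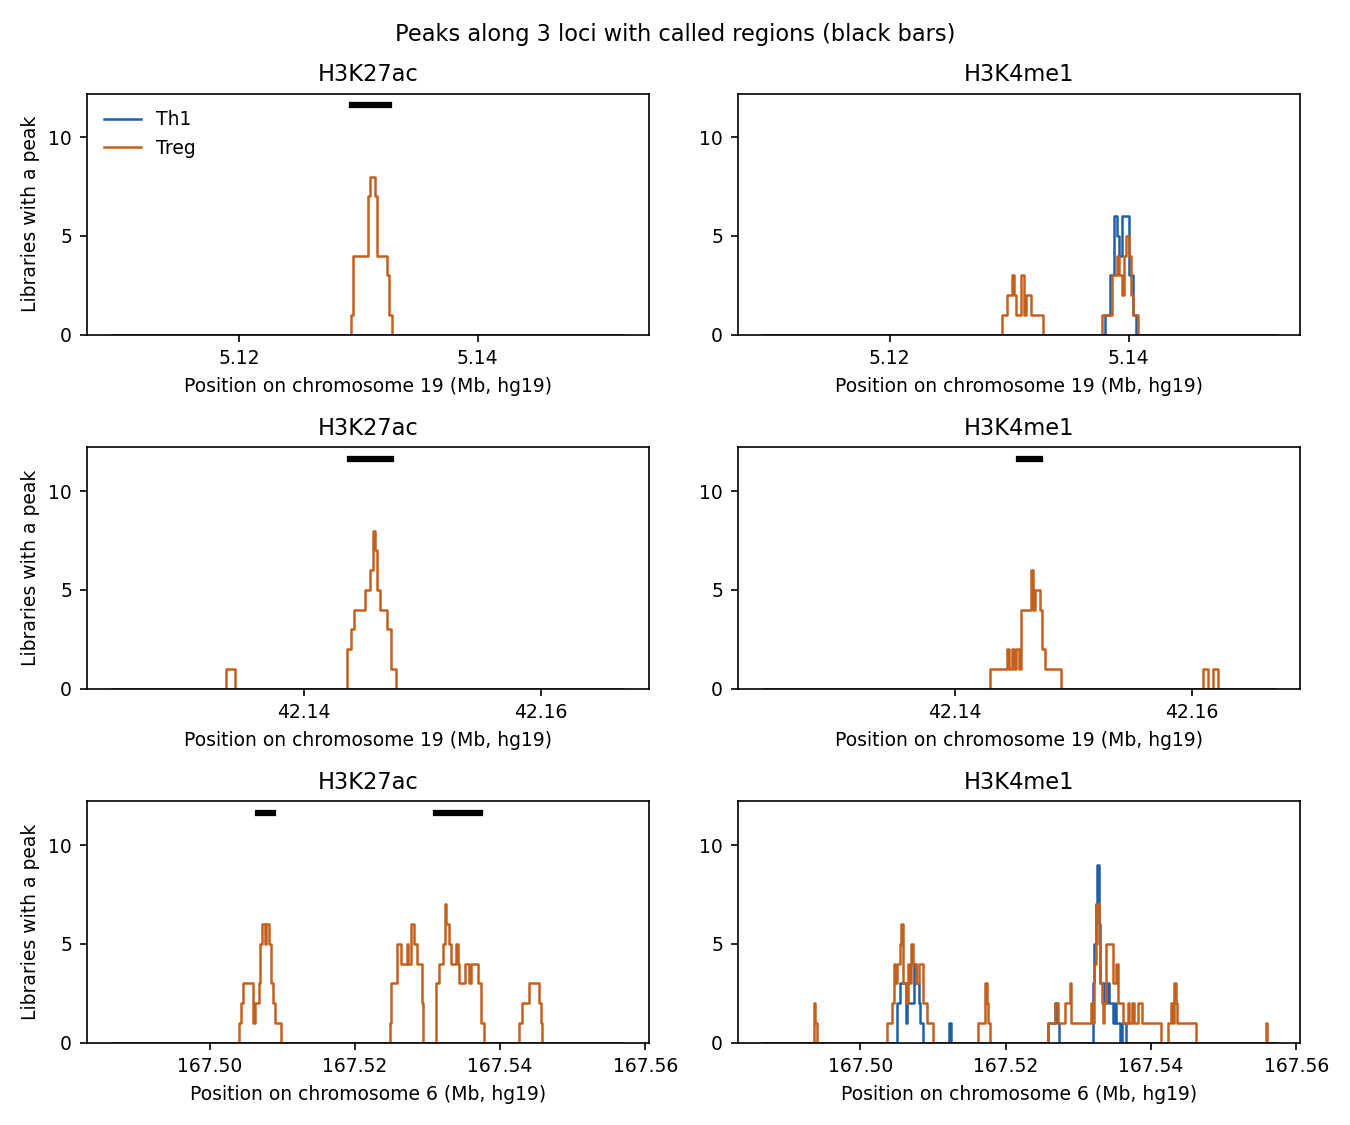
Number of libraries with a peak at positions 200 bp apart (Mb, hg19) around all called H3K27ac regions, 2 stretches of chromosome 19 and 1 of chromosome 6, for H3K27ac (left) and H3K4me1 (right), in Th1 and Treg; black bars are regions called for the mark of the panel. H3K27ac peaks were present in 0 Th1 libraries along all 3 stretches, while H3K4me1 peaks were present in up to 9 Th1 and up to 7 Treg libraries at 1 position of the chromosome 6 stretch.

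The share of H3K27ac peaks that overlapped an H3K4me1 peak of the same donor and cell type was 44.3 ± 22.5% in Th1 (SD, n = 11) and 30.5 ± 28.3% in Treg (SD, n = 11). The difference did not pass a test that leaves out the pairing by donor (permutation p = 0.22). Within donors the same difference of 13.8 percentage points passed the test without adjustment (exact sign-flip permutation p = 0.0146 with the donor as a block). The other list measures did not pass with the donor as a block (exact sign-flip permutation, unadjusted p from 0.13 to 0.574). The difference in share was 7.15 percentage points with a score of at least 100 and 5.44 with 50% of the H3K27ac peak covered. With labels permuted within width classes, which also leaves out the pairing, the permutation p was 0.121. The share was not adjusted for the length that the H3K4me1 lists covered, which averaged 23.8 Mb in Th1 and 15.8 Mb in Treg. Treg control replicate 2, with 87.2 Mb, had a share of 95.5%, and Th1 control replicate 2, with 76.1 Mb, 89.4%. Th1 T1D replicate 4, with 47.5 Mb, had 39.3%. A difference in list size is thus not told apart from one between the cell types.

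Between T1D and control donors, 0 H3K27ac regions were called in Th1 and 0 in Treg by the exact conditional test. In Th1, 87 regions had an unadjusted p under 0.05, 68 higher in T1D and 19 in controls, and Fisher's exact test gave 2, both higher in controls. The balance turned without control replicate 3 (52 and 81) or 5 (67 and 72) and with lists of equal length (13 and 14). The number was 154 without control replicate 4 and 131 without T1D replicate 6. The smallest p-values, none of which passed, belonged to regions on chromosome 3 at 111334313, chromosome 6 at 150262634 and chromosome 9 at 139426129, each with a peak in 6 of 6 T1D and 2 of 5 control libraries (exact test, adjusted p = 1), and, higher in controls, to regions on chromosome 2 at 182006835 (0 of 6 and 4 of 5), chromosome 11 at 128140834 (1 of 6 and 5 of 5) and chromosome 1 at 92780711 (0 of 6 and 3 of 5). In Treg, 500 regions had an unadjusted p under 0.05, 193 higher in T1D and 307 in controls, and Fisher's exact test gave 8, of which 7 were higher in T1D. With the width class as a stratum the number was 281, and among lists of wide peaks alone it was 168. With 50% coverage 1 region was called, higher in controls (exact test, adjusted p = 0.039), and 159 had an unadjusted p under 0.05, 11 higher in T1D and 148 in controls. The number was 196 with a score of at least 100 (56 and 140) and 112 with lists of equal length (28 and 84). It was 157 without T1D replicate 1, 225 without control replicate 4, 269 without control replicate 1 and 303 without T1D replicate 4. The balance turned without T1D replicate 3 (212 higher in T1D, 181 in controls) or 4 (204 and 99) and over regions of at least 6 libraries (193 and 184). Regions on chromosome 1 at 151512418, chromosome 3 at 110789535 and chromosome 9 at 139221345 had a peak in 5 of 6 T1D and 0 of 5 control libraries (exact test, adjusted p = 1). A region on chromosome 15 at 30917547 had a peak in 1 of 6 T1D and 5 of 5 control libraries (exact test, adjusted p = 0.364), and regions on chromosome 1 at 118277667 and chromosome 2 at 54280098 in 0 of 6 and 3 of 5 (exact test, adjusted p = 0.909). None of these passed.

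In H3K4me1, 0 regions were called between T1D and control donors in either cell type by the exact conditional test. In Th1, 868 regions had an unadjusted p under 0.05, 594 higher in T1D and 274 in controls, against 459 with the width class as a stratum, 301 and 158. The balance turned by Fisher's exact test without library weights (5 higher in T1D, 274 in controls), among lists of narrow peaks alone (55 and 180) and without T1D replicate 2 (249 and 377) or 5 (263 and 313). The number was 460 without T1D replicate 3, 486 without T1D replicate 1, 489 without control replicate 3, 501 without control replicate 1 and 576 without T1D replicate 5. Regions on chromosome 11 at 46363207 and chromosome 16 at 57509890 had a peak in 5 of 6 T1D and 0 of 5 control libraries, and a region on chromosome 7 at 149571152 in 6 of 6 and 1 of 5. Higher in controls were regions on chromosome 1 at 199058403, chromosome 2 at 28767144 and chromosome 2 at 46667147, each with 0 of 6 and 5 of 5 libraries. They too were tied (exact test, unadjusted p = 0.00493 for each). In Treg, 613 regions had an unadjusted p under 0.05, 532 higher in T1D and 81 in controls, while with the width class as a stratum 308 were higher in T1D and 154 in controls. By Fisher's exact test without library weights the balance was reversed, with 0 of 834 higher in T1D. Among lists of narrow peaks alone 138 were higher in T1D and 159 in controls. Without T1D replicate 3 there were 381, all higher in T1D. A region on chromosome 5 at 175299128 had a peak in 4 of 6 T1D and 0 of 5 control libraries, and regions on chromosome 1 at 154756811 and chromosome 3 at 119040767 in 5 of 6 and 1 of 5. The last 2 reversed direction with 50% coverage. Regions on chromosome 1 at 6257579, 109047483 and 172348647 had a peak in 0 of 6 T1D and 5 of 5 control libraries. These 3 shared the same p (exact test, unadjusted p = 0.0228), and ties were ordered by genome position. All of these H3K4me1 regions had an adjusted p of 1 and none passed.

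The H3K4me1 lists of Treg cells covered 5.21 ± 4.64 Mb in T1D donors (SD, n = 6) and 28.4 ± 34.4 Mb in control donors (SD, n = 5), and this difference passed an exact permutation test without adjustment (p = 0.0346). It did not pass with labels permuted within width classes (permutation p = 0.0713); 5 of 6 T1D lists and 3 of 5 control lists were narrow. Leaving out T1D replicate 1, 2, 4, 5 or 6, or control replicate 2 or 5, also ended the call, and the difference was -8.55 Mb without control replicate 2 against -23.2 Mb with all donors. In Th1 the covered lengths were 16.1 ± 16.3 Mb (SD, n = 6) and 33.2 ± 33.6 Mb (SD, n = 5; exact permutation p = 0.255). With labels permuted within width classes the permutation p was 0.0585. The difference of -17.1 Mb in Th1 was -6.38 Mb without control replicate 2 and -9.61 Mb without control replicate 5. The number of H3K4me1 peaks in Treg was 19073 ± 17757 in T1D (SD, n = 6) and 26635 ± 8576 in control donors (SD, n = 5; exact permutation p = 0.433). Without T1D replicate 3, which had 54421 peaks, the difference was -14632 peaks (exact permutation p = 0.00794). In Th1 the numbers were 23480 ± 11327 and 27516 ± 2087 (exact permutation p = 0.444). The difference of -4036 peaks was -1491 without T1D replicate 6, -2339 without T1D replicate 2, -2420 without T1D replicate 5, -6220 without T1D replicate 3 and -6915 without T1D replicate 1.

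H3K27ac list sizes did not differ detectably between T1D and control donors. Peak numbers were 13414 ± 4155 in T1D and 12636 ± 2818 in control Th1 cells (exact permutation p = 0.771), and 11564 ± 5862 and 10915 ± 3439 in Treg cells (exact permutation p = 0.829). Both directions rested on single donors. The Th1 difference of 777 peaks was -773 without T1D replicate 5, -415 without control replicate 1 and -677 with a score of at least 100. The Treg difference of 649 peaks was -616 without T1D replicate 6, -425 without T1D replicate 3 and -408 without control replicate 1. Covered lengths were 18.2 ± 14.8 Mb and 23.97 ± 6.01 Mb in Th1 (exact permutation p = 0.429) and 21.4 ± 14.98 Mb and 13.1 ± 12.9 Mb in Treg (exact permutation p = 0.331). The Th1 difference of -5.73 Mb was -10.5 Mb without T1D replicate 5, -2.66 Mb without T1D replicate 4 and -2.72 Mb without T1D replicate 2. The Treg difference of 8.38 Mb was 13.95 Mb without control replicate 2 and 4.52 Mb without T1D replicate 6. The share of H3K27ac peaks overlapping H3K4me1 peaks was 33.1 ± 14.5% in T1D and 57.7 ± 24.5% in control Th1 cells (exact permutation p = 0.0736), and 24.5 ± 22.99% and 37.7 ± 35.0% in Treg cells (exact permutation p = 0.487). The Treg difference of -13.2 percentage points was 1.24 without control replicate 2 and -22.0 without T1D replicate 3, and it passed with 50% of the H3K27ac peak covered (-21.4 percentage points, exact permutation p = 0.0325). In Th1 the share passed without T1D replicate 3 (exact permutation p = 0.0317) and without control replicate 3 (exact permutation p = 0.0381). It did not pass with a score of at least 100 (exact permutation p = 0.158), with 50% of the H3K27ac peak covered (exact permutation p = 0.29) or with labels permuted within width classes (permutation p = 0.345). None of these shares was adjusted for the length that the H3K4me1 lists covered. The T1D effect did not differ detectably between the cell types for any of the 5 list measures, with exact permutation p-values from 0.219 to 0.976 and adjusted p-values from 0.563 to 0.976.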

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

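The outlier checks followed a fixed formula, and the tests that weigh explanations below were chosen after the results were seen, while the splits that part every donor pair were set before their own outcome was known. Of 28 groups checked for a library far from the others, 7 were singled out. Chance alone gives about 1 in 20 for independent groups of normally distributed values. The groups here share libraries across measures, so 7 of 28 cannot be set against that rate. In each of the 7, the gap between the far library and its nearest neighbour exceeded Dixon's critical share of the group's range. In Treg T1D cells, replicate 3 had 54421 H3K4me1 peaks against 4532 to 15595 in the other libraries, covered 14.4 Mb against at most 5.41 Mb, and had an overlap share of 68.5% against at most 24.02%. Treg T1D replicate 4 had a median H3K4me1 peak width of 1050 bp against 160 to 222 bp, as the 1 wide list beside 5 narrow ones. In Th1 T1D cells, replicate 4 covered 47.5 Mb with H3K4me1 against at most 18.6 Mb. In H3K27ac, Treg control replicate 2 covered 35.4 Mb against at most 13.01 Mb, and Th1 control replicate 3 had a median peak width of 1499 bp against 1767.5 to 1802 bp.

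For Treg H3K27ac between T1D and control donors, weighed first, the real split gave 500 regions at an unadjusted p under 0.05, more than any of 99 other splits, whose highest was 475, so 1 of 100 splits reached it. Single donors moved this number: it was 157 without T1D replicate 1, 225 without control replicate 4, 269 without control replicate 1 and 303 without T1D replicate 4. With lists of wide and of narrow peaks kept apart, the real split gave 281 regions, and 11 of 100 splits within the classes gave as many, with a highest other of 395. The width of the peaks in the lists may therefore account for much of this excess, and no disease effect on H3K27ac was shown. What produced the width classes was not tested.

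Of the regions called between Th1 and Treg, weighed second, all 12 kept their direction and an unadjusted p under 0.001 by the exact test with the width class as a stratum. Of the 12, 6 no longer passed the adjustment. The limit of 0.001 was set after the regions had been called in the same data. A region with a peak in 0 libraries of a cell type could not reverse its direction. The width class as a stratum thus did not remove these differences, but a part of peak width in them is not excluded. The real split alone, 1 of 100, gave as many as 4 H3K27ac and 8 H3K4me1 calls, with a highest other of 2 and 0 among splits of the 22 libraries and of 3 and 0 among splits that part every donor pair, which reached at most 632 and 1289 regions at an unadjusted p under 0.05 against the real 678 and 1753. No other of the 100 splits reached these counts with all donors, which weighs against chance assignment at no finer a level than 1 in 100. For H3K27ac the lead over the other splits was small, 4 calls against 3 and 678 regions against 632. The donor block called 1 H3K27ac and 0 H3K4me1 regions (exact test, smallest adjusted p = 0.364 for H3K4me1). Without T1D replicate 5 there were 0 H3K27ac calls and 406 regions at an unadjusted p under 0.05, while leaving out each donor in turn gave 3 to 10 H3K4me1 calls. The fullness of the lists, as a trace of read depth, was also weighed. Libraries with a peak were paired with libraries of the other cell type without one. In 12 of 12 called regions, at least 25% of these pairs had the peak in the emptier list. The share was 29.1% to 33.9% for the Th1-higher H3K4me1 regions, 58.9% to 63.6% for the Treg-higher ones and 45.5% to 52.3% for H3K27ac. These shares cannot decide the question, since the weights that chose the regions already allow for fullness. Where all lists of 1 cell type and none of the other have the peak, list fullness alone fixes the share. Read depth, other technical differences and a difference between the cell types stay open.

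In the other T1D comparisons, the numbers at an unadjusted p under 0.05 were set against other splits in the same way. For H3K27ac in Th1, 94 of 100 splits gave 87 or more regions, with a highest other of 325, and for H3K4me1 in Treg 11 of 100 gave 613 or more, with a highest other of 810, so chance could not be excluded. For H3K4me1 in Th1, 4 of 100 splits gave 868 or more, with a highest other of 1102, so few splits reached the real number. It fell to 459 with the width class as a stratum. No splits within the classes were run for this comparison, so whether 459 is still an excess is not known, and no disease effect was shown. Leaving out each donor in turn gave 75 to 154 regions for H3K27ac in Th1, 381 to 702 for H3K4me1 in Treg and 460 to 712 for H3K4me1 in Th1.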

How the results depend on the processing

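The width class settings and the restricted set of regions were chosen after seeing the data. The number of H3K27ac regions called between Th1 and Treg (4) was 0 by Fisher's exact test, with equal lists, with 50% coverage, and in control or T1D donors alone. It was 1 with a score of at least 100, with the donor as a replicate block, with the width class as a stratum, and in lists of wide peaks alone, and 11 over regions of at least 6 libraries, which include all 4. Leaving out each donor in turn gave 0 to 5. The number of H3K4me1 regions called (8) was 0 with a score of at least 100, with equal lists, with the donor block, in control or T1D donors alone, and in lists of wide or of narrow peaks alone. It was 2 by Fisher's exact test, 5 with the width class as a stratum, 13 over regions of at least 6 libraries, of which 4 were among the 8, and 18 over regions able to reach a p under 0.001, which include all 8. Leaving out each donor in turn gave 3 to 10. Control or T1D donors alone left 5 against 5 and 6 against 6 libraries. H3K4me1 lists of wide or of narrow peaks alone left 4 against 3 and 7 against 8. For H3K4me1, the smallest p in these sets lay between 0.00013 and 0.000438 (exact test, unadjusted), against 3.11e-07 with all libraries. With so few libraries, their 0 calls cannot tell a lost difference from a lack of power. The same holds for H3K27ac in control or T1D donors alone. None of the 12 called regions changed direction in any setting where it was found. Tested over the same region, one with a peak in 0 libraries of a cell type could not have done so. With 50% coverage H3K4me1 again had 8 calls, but 0 of them were the regions called above. Between T1D and control donors in Treg, 50% coverage called 1 H3K27ac region; the other settings called 0 in the T1D comparisons. Of 24 T1D regions named above, 0 passed in any setting, and those on chromosome 1 at 154756811 and chromosome 3 at 119040767 reversed with 50% coverage (exact test, adjusted p = 1 for each).

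The T1D minus control difference in H3K27ac peak number, not called in any setting, reversed in Th1 with a score of at least 100 (-677) and in Treg on the log2 scale (-0.0593). Leaving out each donor in turn, it ranged from -773 to 1605 in Th1 and from -616 to 2041 in Treg. The Th1 minus Treg difference ranged from 314 to 2469 in H3K27ac peak number, from 672 to 5086 in H3K4me1 peak number, from -0.115 to 5.87 Mb in H3K27ac covered length and from 4.68 to 10.0001 Mb in H3K4me1 covered length. The T1D minus control difference in H3K4me1 peak number ranged from -6915 to -1491 in Th1 and from -14632 to -4654 in Treg, and in H3K4me1 covered length from -23.9 to -6.38 Mb in Th1 and from -29.1 to -8.55 Mb in Treg. In H3K27ac covered length it ranged from -10.5 to -2.66 Mb in Th1 and from 4.52 to 13.95 Mb in Treg, and in overlap share from -30.7 to -16.6 percentage points in Th1 and from -22.0 to 1.24 in Treg. The H3K4me1 covered length in Treg (-23.2 Mb) lost its call with the width class as a stratum, at the same value. The donor block raised the overlap share between cell types (13.8 percentage points) to an unadjusted call and changed no other size call. The T1D difference in overlap share in Treg was called with 50% of the H3K27ac peak covered (-21.4 percentage points). The causes were not tested. Gene list and promoter alternatives were not run, for lack of an hg19 annotation. Read depth is unknown, so an absent peak sets no upper limit on the mark.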

Other observations

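The tests in this part were chosen after the region results had been seen, and the comparison of splits for the direction of the marks was set before its outcome was known. Autosomes were divided into stretches of 100 kb with at least 3 consensus regions, and each library's share of regions with a peak, minus the share expected from its list size, was compared between Th1 and Treg by a permutation test with Benjamini-Hochberg adjustment over the stretches of a mark. Of 2147 H3K27ac stretches, 10 were called, 3 higher in Th1 and 7 in Treg, and of 4726 H3K4me1 stretches 41 were called, 28 higher in Th1 and 13 in Treg. That test leaves out the pairing of the libraries by donor. With the donor as a block, 0 stretches of either mark were called by exact sign-flip permutation; the smallest p this can give, 0.000977, would have been needed in at least 42 H3K27ac or 93 H3K4me1 stretches and was reached in 14 and 39. The highest blocked p among the called stretches was 0.00391 for H3K27ac and 0.00488 for H3K4me1 (exact sign-flip permutation, unadjusted). With labels permuted within width classes, 10 H3K27ac and 49 H3K4me1 stretches were called, among them 10 of the 10 and 40 of the 41. The stretches named here are those with the smallest p in each direction, 2 per mark and direction, with ties broken by the size of the difference. Stretches use the same libraries and regions as the region tests. Those named on chromosomes 6, 11 and 15 hold regions called above for the same mark, so they are no independent evidence for them. Higher in Treg in H3K27ac, chromosome 6 from 167500001 to 167600000 held 5 regions, with peaks in 0% of them in Th1 and 47.3% in Treg libraries (permutation p = 1e-05, the smallest the resamples can give, adjusted p = 0.0215), and chromosome 20 from 35600001 to 35700000 had 18.2% and 37.9% (permutation, adjusted p = 0.0286). Higher in Th1 in H3K27ac, chromosome 20 from 24900001 to 25000000 had 100% and 54.5% (permutation, adjusted p = 0.0286), and chromosome 19 from 18500001 to 18600000 had 62.1% and 33.3% (permutation, adjusted p = 0.0334). In H3K4me1, chromosome 15 from 26000001 to 26100000 had peaks in 81.8% of 3 regions in Th1 and 21.2% in Treg, and chromosome 11 from 36400001 to 36500000 in 58.4% and 7.79% of 7 regions (permutation, adjusted p = 0.00945 for each). Higher in Treg in H3K4me1, chromosome 3 from 33000001 to 33100000 held 18 regions, with 37.4% in Th1 and 60.1% in Treg (permutation, adjusted p = 0.00945), and chromosome 2 from 198800001 to 198900000 had 0% and 45.5% (permutation, adjusted p = 0.0135).

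Where an H3K27ac region overlapped an H3K4me1 region, the marks could be compared. Of 20191 overlapping pairs, 91 had an unadjusted p under 0.05 in both marks between Th1 and Treg, and 88 of these (96.7%) differed in the same direction, 35 higher in Th1 and 53 in Treg. The hypothesis that library differences shared by both marks of a donor and cell type give such a share was set against splits that part every donor pair. As high a share was found in 14 of 100 splits, so shared library differences may produce it and are not excluded. Those splits held few pairs: the highest number in any other split was 25, with a median of 5, and 1 of 100 splits, the real one, reached 91.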
